A study of Rattus norvegicus with 25 samples.

How the data were processed

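RNA-seq was measured in the hippocampus of adult male Sprague-Dawley rats aged 6 to 7 weeks. Per the labels, RNA was extracted with a fibrous tissue mini kit and made into polyA-selected libraries with the TECAN Universal Plus kit. The 25 libraries fell into 5 groups of 5: sham surgery with vehicle, and controlled cortical impact (CCI) with vehicle or with 1 of 3 thymus supplements. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries. The dose, the time after injury and the side of the brain were not given in the sources used here.

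The main table held the authors' deposited read counts per gene, as whole numbers with nothing normalised, 1 column per library, with the gene positions beside them. The submitters' processing notes name STAR, Salmon, featureCounts and DESeq2 without versions or roles, and the genome build mRatBN7.2. The strand setting of the counting was not given in the sources used here, so values of overlapping genes, antisense genes and near-identical paralogs are uncertain. For each CCI group the authors deposited 1 table with a log2 fold change over the control, per the file headers. The same tables held the authors' DESeq2 p-values, raw and adjusted, per the file headers. Their fold changes followed the group over the 5 Vehicle-sham libraries of the count table. Positions were those of the deposited table on mRatBN7.2, counted from 1, from the start of the first exon to the end of the last. Whether a read fell in a coding or an untranslated part is unknown from gene counts.

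The count table listed 34322 genes. Of these, 7 very long genes had empty cells and were left out. Library totals ran from 27.3 to 44.9 M counts (M, 1e6), with a median of 32.8 M. At these depths the spread between libraries, not counting error, set the precision, since pairs of libraries of 1 group differed by 23.7 to 682 times the counting variance (chi-square per degree of freedom). Reads without molecular identifiers are not independent molecules, so that figure covers counting error only.

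The tests used edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter by group and the robust quasi-likelihood F test. All 25 libraries entered 1 fit with a mean per group, so that the 12 contrasts shared 1 estimate of the spread. After the filter 21064 genes were tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 1053 genes given as by chance at an unadjusted p under 0.05 are 0.05 of the genes tested. Random splits of the same libraries gave counts far from it, from 99 to 5551 for the mean of the 4 CCI groups. An excess or shortfall against 1053 alone therefore carries no weight. Mean levels are CPM (counts per 1e6 counts of the library) after TMM scaling, computed here, with the standard deviation (SD) over libraries. Fold changes are on the log2 scale of the edgeR fit with their standard error (SE). In all comparisons, the first-named group is over the second.

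Of 42 gene lists for cell types, pathways and neighbouring tissues, 41 had at least 5 tested members. They were tested in 7 comparisons with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists of each comparison. Each list was tested again with a correlation estimated from the data, and with fry. An injury score per library was the mean log2 CPM of the genes called higher in the mean of the 4 CCI groups over sham minus that of the genes called lower, centred on the sham mean. Its group differences were tested with an exact two-sided permutation test of 5 against 5 libraries, adjusted over the 3 supplements.

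The comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. The rule took Gfap, Cd68 and Bdnf in every comparison. In each CCI group over sham it took the genes of largest change among those called, at a mean of at least 1 CPM and without overlap between the groups. In comparisons between CCI groups it took the genes of smallest p, reported as not passing where fewer than 3 passed. In each of up to 10 called lists it took the 2 members of smallest p, and a gene named in 1 comparison was allowed in the others. Genes outside this rule are said to have been chosen after their values were seen.

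The alternatives were DESeq2 size factors, no filter on low counts, a filter at 1 CPM, a replicate block, the number in each library's title as a covariate, DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the groups compared, a looser threshold, and leaving out each library. A fit without 2 sham libraries, a fit without 4 libraries and the mitochondrial rRNA share as a covariate were added after the data were seen.

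The scripts were tested on simulated data. For Vehicle-CCI versus Vehicle-sham, counts of 21064 genes were simulated from the real means and library sizes, and 20893 passed the filter. The test called 48 of 100 genes changed by a log2 fold of 1, and 88 of the 99 tested that were changed by a log2 fold of 2, all with the right sign. Of 20694 unchanged genes it called 4, and 4.69% had an unadjusted p under 0.05. In a simulation of the same comparison with 21064 genes, a list shifted by 0.5 on the log2 scale was called by camera (adjusted p = 7.33e-14) and 0 of the other lists were. Genes were drawn independently of each other there, so it cannot show how often camera errs where genes of a list vary together.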

Results

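The data were gene counts from the hippocampus of rats with a traumatic brain injury or a sham operation. Controlled cortical impact (CCI) drives a piston onto the exposed cortex, which lies over the hippocampus. Of the 5 groups, Vehicle-sham had no impact, and Vehicle-CCI had the impact without a supplement. TD-CCI, TCF-CCI and TNF-CCI had the impact and were given a thymus supplement, named in the labels as thymus, thymus cytosolic factor and thymus nuclear factor. TNF here names that supplement and not the cytokine tumour necrosis factor. The series title and design text place the 3 supplements beside sham controls and ask about recovery after the injury.

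Each group had 5 libraries. Totals averaged 31.5 ± 2.78 M counts (M, 1e6; SD, n = 5) in Vehicle-sham, 32.6 ± 0.829 M in Vehicle-CCI, 32.4 ± 3.34 M in TD-CCI, 30.9 ± 2.21 M in TCF-CCI and 38.3 ± 3.96 M in TNF-CCI. The share of counts on the 2 mitochondrial ribosomal RNA genes, which polyA selection should keep low, averaged 11.6 ± 9.62% in Vehicle-sham and 4.87 ± 3.41% in TNF-CCI. It averaged 7.89 ± 1.46% in Vehicle-CCI, 6.59 ± 0.93% in TD-CCI and 7.57 ± 1.68% in TCF-CCI. Among the sham libraries the share ran from 2.18% to 25.63%, the highest in Vehicle-sham 2, with 17.26% in Vehicle-sham 3. Vehicle-sham 2 also had the lowest TMM factor of its group (0.645), and counts on 622 olfactory, vomeronasal and taste receptor genes, which brain tissue should hardly express. Principal components 1 and 2 of the log2 CPM values held 25.1% and 16.8% of the variance.

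**Figure D1:**
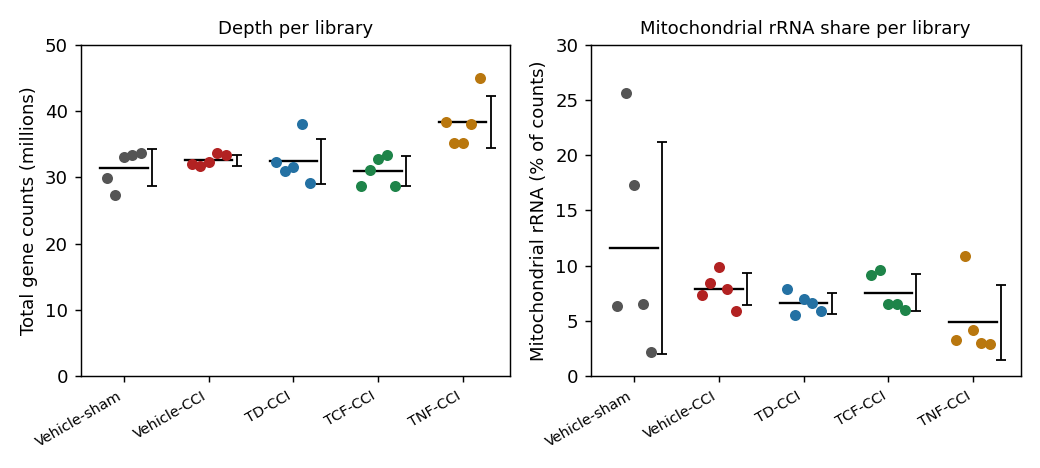
Total gene counts in M (1e6) (left) and mitochondrial rRNA as a percentage of all counts (right) for each of the 25 libraries. Points are libraries, horizontal lines are group means and vertical bars are SD (n = 5); the sham libraries spread from 2.18% to 25.63%, and the TNF-CCI group had the highest mean total (38.3 M).

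The mean of the 4 CCI groups was first compared with sham, for the average response to injury with or without a supplement. Of these groups 3 had a supplement and the sham group had vehicle only. Injury and supplement therefore cannot be told apart in this mean, nor in a supplement group over sham. Members of the list for activated microglia, the resident phagocytes of the brain, were among the genes that rose. Cd68, a lysosomal glycoprotein of phagocytes (chromosome 10, 54381814 to 54383693), averaged 6.75 ± 4.35 CPM in the CCI libraries (SD, n = 20) and 1.31 ± 0.541 CPM in sham (n = 5), a log2 fold change of 2.28 ± 0.5 (SE; edgeR adjusted p = 0.0222), and 18 of 20 CCI libraries lay above every sham library. Of 22 tested members of the microglia activation list, 13 rose and 0 fell, and 17 were higher and 1 lower when adjusted over the list alone. Among them were the secreted phosphoprotein Spp1 (log2 fold change 3.5 ± 0.73), the glycoprotein Gpnmb (3.07 ± 0.64), the galectin Lgals3 (2.67 ± 0.59) and the lipid receptor Trem2 (1.3 ± 0.3). Of 11 markers of resting microglia, 4 rose (6 adjusted over the list alone), among them Cx3cr1, Csf1r and Aif1. In the complement list 6 of 18 rose (13 adjusted over the list alone), with C3, on which all complement pathways converge, at 2.25 ± 0.47 and Serping1, the C1 inhibitor, at 2.42 ± 0.53. Cd4, which rat macrophages and microglia carry as well as T cells, rose by 2.05 ± 0.44, and Cd8a by 2.5 ± 0.69 at a low level (0.502 ± 0.371 against 0.0749 ± 0.0796 CPM). They were the 2 of 11 lymphocyte markers that rose (3 higher and 2 lower adjusted over the list alone; median 0.07, 6 above 0).

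Some reactive astrocyte genes rose as well. Gfap, the intermediate filament of astrocytes (chromosome 10, 87852891 to 87861631), averaged 2770 ± 1630 CPM in CCI (n = 20) against 1050 ± 392 in sham (n = 5), a log2 fold change of 1.33 ± 0.34 (edgeR adjusted p = 0.0289), above every sham library in 16 of 20. Vimentin (Vim, 2.16 ± 0.48), the copper-binding ferroxidase Cp (1.97 ± 0.46), Nes, Cd44, Osmr and Lcn2 made up the 7 of 20 that rose (15 adjusted over the list alone). In the fibroblast and matrix list, collagen Col1a1 (0.96 ± 0.21), fibronectin Fn1 (1.01 ± 0.22) and Fmod rose, 3 of 20 (9 adjusted over the list alone). Of 23 cytokine and chemokine genes, Tgfb1 (1.39 ± 0.34) and Cxcl1 (2.29 ± 0.67, at a low level of 0.564 ± 0.582 against 0.107 ± 0.0218 CPM) rose, 12 when adjusted over the list alone. The metal-binding Mt1 and Mt2A rose by 0.95 ± 0.23 and 0.94 ± 0.26, and the axonemal dynein Dnah12, of motile cilia, by 1.53 ± 0.33.

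Among the falling genes were members of neuronal and sterol synthesis lists, for which no list test was run in this comparison. Bdnf, a neurotrophin (chromosome 3, 96165042 to 96215621), averaged 27.9 ± 10.4 CPM in CCI (n = 20) and 49.3 ± 18 in sham (n = 5), a log2 fold change of -0.83 ± 0.2 (edgeR adjusted p = 0.0251). It lay below the sham mean in 19 of 20 CCI libraries, and below every sham library in 11 of 20. Of 21 excitatory synapse genes, 5 fell (15 adjusted over the list alone), among them the kinase Camk2a (2310 ± 762 CPM in CCI, n = 20, against 3920 ± 1050 in sham, n = 5; -0.77 ± 0.22), the AMPA receptor subunit Gria2 (-0.62 ± 0.16) and the scaffold Homer1 (-0.66 ± 0.16). Of 12 markers of CA2 and CA3 pyramidal neurons, Bok, Cpne4, Nptx1 and Elavl2 fell (5 adjusted over the list alone). That list was mixed, with a median of -0.22 and 5 of 12 above 0. All 9 markers of CA1 neurons lay below 0 (median -0.43), and 0 of them passed (3 adjusted over the list alone). Of 16 interneuron markers, Pvalb, Kcnc2 and Cnr1 fell (5 adjusted over the list alone). In the cholesterol synthesis list 6 of 18 fell (10 adjusted over the list alone), with Hmgcs1, the cytosolic HMG-CoA synthase, at -1.01 ± 0.2 and Idi1 at -1.01 ± 0.25. Of 24 nuclear genes of oxidative phosphorylation 5 fell (12 adjusted over the list alone), and 0 of 22 ribosomal protein genes changed. The medians of the latter 2 lists were -0.41 and -0.34, and without Vehicle-sham 2, the library of highest mitochondrial rRNA share, -0.22 and -0.02. Without it several members named here moved towards 0 by over 1.5 times: Hmgcs1 to -0.6, Idi1 to -0.54, Homer1 to -0.39, Elavl2 to -0.46, Pvalb to -0.4 and Cnr1 to -0.39, while Bdnf was at -0.59, Gria2 at -0.42 and Camk2a at -0.73. The interneuron median went from -0.23 to -0.12. That library was the highest of all 25 in 86.9% of the falling genes, against 21.8% of all tested genes.

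In all, edgeR called 1248 genes in this comparison, 472 higher and 776 lower, so that 37.8% were higher. With limma voom and sample quality weights 642 of 1299 called genes were higher (49.4%). The count rested on single libraries. It fell to 14 without Vehicle-sham 2, a set that held Sulf1, Tmem114, Enox2, Dnajb13 and Cd63 and neither Cd68, Gfap nor Bdnf (edgeR adjusted p = 0.0743, 0.109 and 0.179). It was 2007, 671 and 761 without Vehicle-sham 1, 3 or 4, 653 and 2117 without Vehicle-CCI 1 or 4, 734 and 697 without TD-CCI 1 or 3, 784 and 634 without TCF-CCI 1 or 3, and 1964 and 747 without TNF-CCI 2 or 5. Without Vehicle-sham 2 and 3 together it was 0 (edgeR; 168 with the mitochondrial rRNA share as a covariate).

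**Figure D2:**
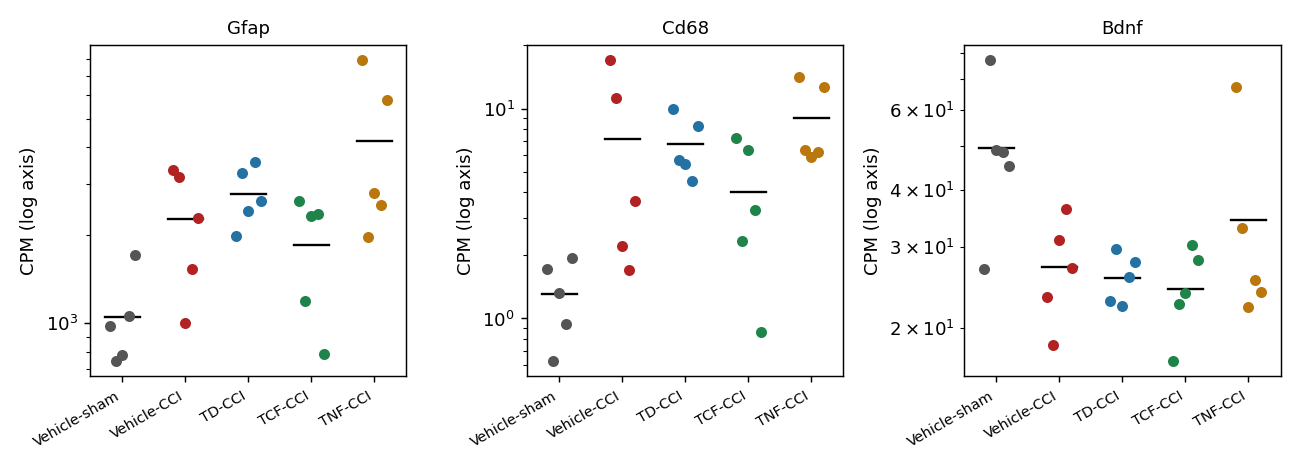
Gfap, Cd68 and Bdnf in CPM (log axis) for each of the 25 libraries by group. Points are libraries and horizontal lines are group means (n = 5); group means of Gfap ran from 1050 CPM in Vehicle-sham to 4200 CPM in TNF-CCI, and those of Bdnf from 24.3 CPM in TCF-CCI to 49.3 CPM in Vehicle-sham.

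Some genes parted the 20 CCI libraries from the 5 sham libraries without overlap, a set chosen after its values were seen. There were 17, 9 higher and 8 lower, where chance would give 0.793. Sulf1, a sulfatase that edits heparan sulfate (chromosome 5, 6362896 to 6526174), averaged 11.8 ± 3.97 CPM in CCI (SD, n = 20) and 3.68 ± 1.12 in sham (n = 5; 1.67 ± 0.27, edgeR adjusted p = 0.0067). Tmem114 (-1.27 ± 0.19) and Enox2 (-0.84 ± 0.13) were the lower genes at the same edgeR adjusted p of 0.0067. The others called higher were Myo7a, Plekhg6, Cnr2, Sema3b, Stxbp2, Galns, LOC120094353 and Sting1, and those called lower Nr4a3, Epha6, Plcxd2, Klhl34 and Arid1b. LOC120095907 was lower without passing (-0.88, edgeR adjusted p = 0.0663).

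**Figure D3:**
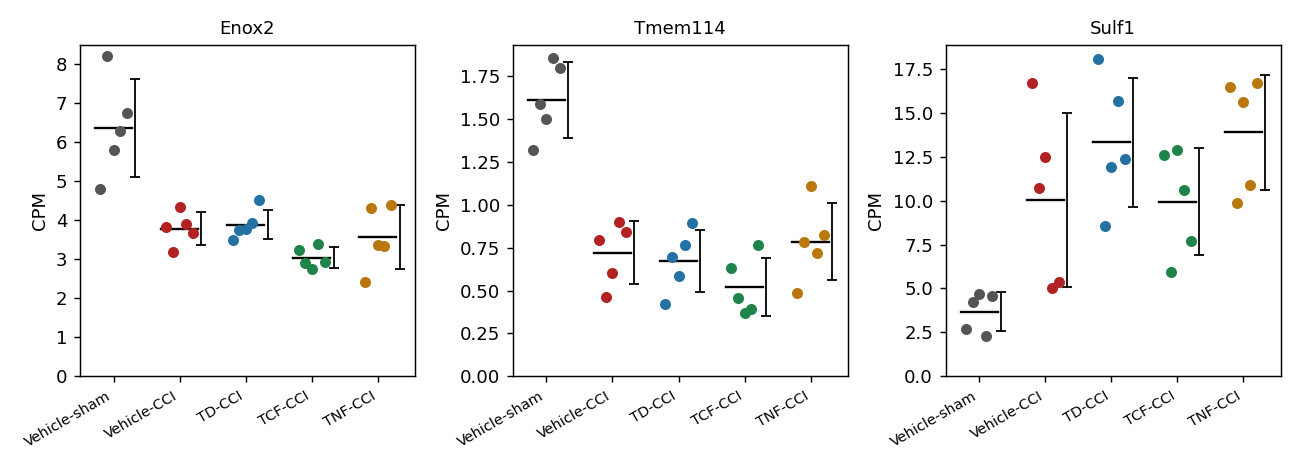
Enox2, Tmem114 and Sulf1 in CPM for each of the 25 libraries by group. Points are libraries, horizontal lines are group means and vertical bars are SD (n = 5); the sham mean was 6.36 CPM in Enox2, 1.62 in Tmem114 and 3.68 in Sulf1.

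Vehicle-CCI was compared with Vehicle-sham for the effect of the injury without a supplement. Microglial, complement, astrocyte and MHC class II lists were higher, and no single gene passed. Cd68 averaged 7.16 ± 6.74 CPM against 1.31 ± 0.541 (SD, n = 5 each), a log2 fold change of 2.43 ± 0.57 (edgeR adjusted p = 0.132). Gfap averaged 2260 ± 1010 against 1050 ± 392 CPM (1.1 ± 0.39, edgeR adjusted p = 0.244), and Bdnf 27.2 ± 6.93 against 49.3 ± 18 CPM (-0.86 ± 0.27, edgeR adjusted p = 0.203), lower than the sham mean in 5 of 5. The groups overlapped in Bdnf, with 26.9 CPM in Vehicle-sham 1 and 36.3 in Vehicle-CCI 4. The microglia activation list had a median of 1.31 with 20 of 22 members above 0 (camera adjusted p = 7.87e-10; 0.281 with an estimated correlation), and 17 members passed when adjusted over the list alone. Among its members Spp1 had a log2 fold change of 3.59 ± 0.8 and Lgals3 of 2.88 ± 0.66. Reactive astrocyte genes had a median of 0.97 (camera adjusted p = 7.67e-08; adjusted p = 0.281 with an estimated correlation; 8 adjusted over the list alone) and complement genes 0.93 (camera adjusted p = 1.02e-07; adjusted p = 0.303 with an estimated correlation; 11 adjusted over the list alone). The 9 MHC class II genes, of antigen presentation, all lay above 0, with a median of 1.01 (camera adjusted p = 0.00256; adjusted p = 0.428 with an estimated correlation; 0 adjusted over the list alone).

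Lower in the same comparison were excitatory synapse genes, with a median of -0.47 and 20 of 21 below 0 (camera adjusted p = 3.22e-09; adjusted p = 0.281 with an estimated correlation; 0 adjusted over the list alone). Camk2a had a log2 fold change of -0.89 ± 0.3 and Homer1 of -0.6 ± 0.21. All 18 cholesterol synthesis genes lay below 0, with a median of -0.45 (camera adjusted p = 1.59e-08; adjusted p = 0.281 with an estimated correlation; 7 adjusted over the list alone), Hmgcs1 at -0.9 ± 0.28. All 18 synaptic vesicle genes lay below 0 too, with a median of -0.35 (camera adjusted p = 2.74e-05; adjusted p = 0.428 with an estimated correlation). Without Vehicle-sham 2 Homer1 was at -0.34 and Hmgcs1 at -0.49. Markers of the ciliated ependyma had a median of 0.68 (camera adjusted p = 1.02e-05; adjusted p = 0.359 with an estimated correlation), with Dnah12 at 1.5 ± 0.38. The 24 nuclear oxidative phosphorylation genes all lay below 0 (median -0.28, camera adjusted p = 8.05e-05; adjusted p = 0.471 with an estimated correlation), and lost the call without Vehicle-sham 2 (camera adjusted p = 0.0755).

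For single genes of Vehicle-CCI versus Vehicle-sham edgeR called 0. At an unadjusted p under 0.05 there were 2669, where 0.05 of the tested genes is 1053. Other splits of the same libraries gave 601 to 3850, so 2669 does not exceed what regrouping gives. DESeq2 called 245 and limma voom with sample quality weights 0. Without Vehicle-CCI 4, which had the lowest Cd68 level of its group (1.7 CPM), edgeR called 368. Of 41 lists camera called 22, of which 14 were called in the same direction in all 15 alternative fits with the preset correlation.

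**Figure D4:**
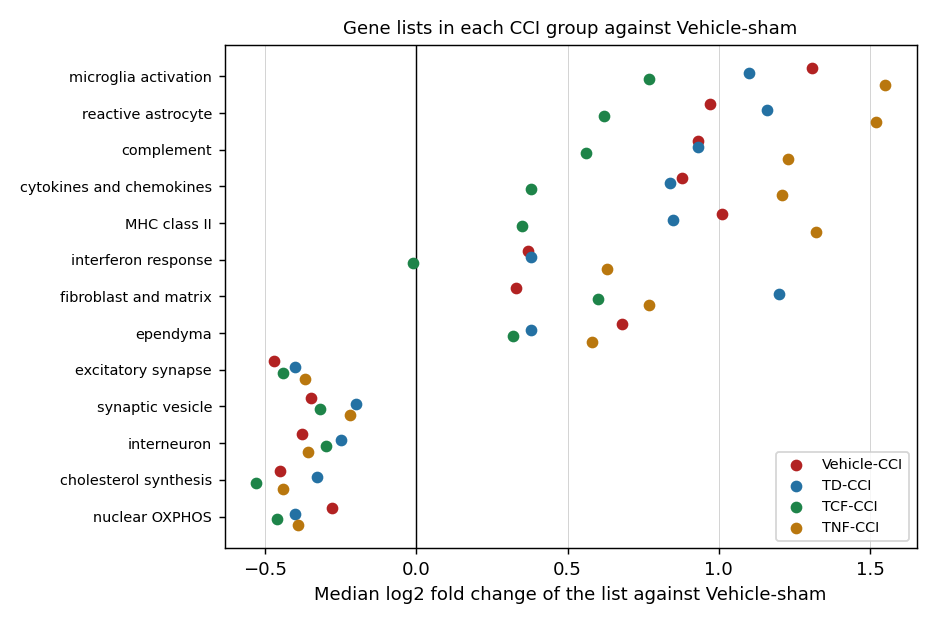
Median log2 fold change of the tested members of 13 gene lists in each CCI group against the same 5 Vehicle-sham libraries. Each point is 1 list in 1 CCI group; the microglia activation medians were 1.31, 1.1, 0.77 and 1.55 in Vehicle-CCI, TD-CCI, TCF-CCI and TNF-CCI, and all 4 share their control libraries.

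TD-CCI versus Vehicle-sham is 1 of the 3 comparisons that the series design states. Gfap averaged 2770 ± 632 CPM (SD, n = 5) against 1050 ± 392 (1.39 ± 0.39, edgeR adjusted p = 0.154), above every sham library in 5 of 5. Cd68 averaged 6.79 ± 2.27 CPM (2.35 ± 0.57, edgeR adjusted p = 0.151) and Bdnf 25.7 ± 3.2 CPM (-0.94 ± 0.27, edgeR adjusted p = 0.16). Gpnmb averaged 60.1 ± 13.6 CPM against 5.5 ± 3.85, a log2 fold change of 3.44 ± 0.72 (edgeR adjusted p = 0.124). The extracellular matrix was higher, with a median of 1.2 over 20 fibroblast and matrix genes (camera adjusted p = 2.38e-08; adjusted p = 0.276 with an estimated correlation), and 10 passed when adjusted over the list alone. Col1a1, a chain of type I collagen (chromosome 10, 79883622 to 79900625), had a log2 fold change of 1.42 ± 0.25 (edgeR adjusted p = 0.0533) and Fn1 of 1.34 ± 0.26. Microglia activation genes had a median of 1.1 (camera adjusted p = 1.79e-10; adjusted p = 0.276 with an estimated correlation; 16 higher and 1 lower adjusted over the list alone), and reactive astrocyte genes 1.16, with all 20 above 0 (camera adjusted p = 1.79e-10; adjusted p = 0.276 with an estimated correlation; 13 adjusted over the list alone). The endothelium list had a median of 0.65 (camera adjusted p = 1.07e-05; adjusted p = 0.377 with an estimated correlation; 8 higher and 1 lower adjusted over the list alone), with the receptor Tek at 0.65 ± 0.18 and the cadherin Cdh5 at 1.09 ± 0.33.

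Nuclear oxidative phosphorylation genes were lower in TD-CCI, with a median of -0.4 and 23 of 24 below 0 (camera adjusted p = 7.26e-08; adjusted p = 0.394 with an estimated correlation; 5 adjusted over the list alone), beside a mitochondrial rRNA share of 6.59% in TD-CCI and 11.6% in sham. Excitatory synapse genes had a median of -0.4 (camera adjusted p = 1.07e-05; adjusted p = 0.286 with an estimated correlation), with Homer1 at -0.62 ± 0.21 (-0.35 without Vehicle-sham 2) and Gria2 at -0.61 ± 0.21, each below every sham library in 5 of 5. Of 41 lists camera called 20, and 12 in all 15 alternative fits with the preset correlation. Markers of the thalamus, which lies under the hippocampus, were among the 20 (median 0.49, camera adjusted p = 0.0181; adjusted p = 0.377 with an estimated correlation), and not without TD-CCI 4 (camera adjusted p = 0.209), nor without Vehicle-sham 1 (0.066) or 5 (0.0614). TD-CCI 4 held 115 CPM of the thalamic transporter Slc17a6 and 92.4 CPM of Tcf7l2.

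Over single genes edgeR called 0 in TD-CCI versus Vehicle-sham, with 3474 at an unadjusted p under 0.05. DESeq2 called 244, and limma voom with sample quality weights 2, Sulf1 and Tmem114. The smallest edgeR adjusted p was 0.0533, shared by Col1a1, the apelin receptor Aplnr (3.15) and the heparan sulfate sulfatase Sulf1 (1.86), the last 2 chosen after their values were seen. Without TD-CCI 2 edgeR called 2 genes, Sulf1 and Col1a1. Leaving out Vehicle-CCI 1, 3, 4 or 5, TCF-CCI 2, 3 or 5, or TNF-CCI 4, which enter only the shared spread, gave between 1 and 4. An edgeR fit of only the groups compared and a replicate block called more genes than these, with counts given under the processing.

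In TCF-CCI versus Vehicle-sham 3 genes passed, all lower. Enox2, a surface NADH oxidase (chromosome X, 128270941 to 128593074), averaged 3.04 ± 0.268 CPM against 6.36 ± 1.25 (SD, n = 5 each; log2 fold change -1.06 ± 0.17, edgeR adjusted p = 0.029). Tmem114, a transmembrane protein (chromosome 10, 7168998 to 7185251), averaged 0.523 ± 0.169 against 1.62 ± 0.218 CPM (-1.63 ± 0.27, edgeR adjusted p = 0.029). Dnajb13, a cochaperone of ciliary axonemes (chromosome 1, 154848586 to 154863042), averaged 13.7 ± 0.51 against 26.3 ± 3.48 CPM (-0.94 ± 0.16, edgeR adjusted p = 0.0301). In each gene all 5 TCF-CCI libraries lay below every sham library. Of all tested genes 3.55% had no overlap between these groups, and chance gives 0.794%. Gfap averaged 1860 ± 814 CPM (0.82 ± 0.39, edgeR adjusted p = 0.268), Cd68 4.02 ± 2.7 CPM (1.59 ± 0.56, edgeR adjusted p = 0.18) and Bdnf 24.3 ± 5.25 CPM (-1.02 ± 0.27, edgeR adjusted p = 0.152).

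The lists of lowest p in TCF-CCI were lower ones. All 24 nuclear oxidative phosphorylation genes lay below 0, with a median of -0.46 (camera adjusted p = 2.27e-07; adjusted p = 0.557 with an estimated correlation; 11 adjusted over the list alone), Ndufb8 at -0.68 ± 0.21 and Sdhb at -0.57 ± 0.19 (-0.41 and -0.28 without Vehicle-sham 2). The mitochondrial rRNA share averaged 7.57% in TCF-CCI against 11.6% in sham, with medians of 6.55% and 6.58%. All 18 cholesterol synthesis genes lay below 0 (median -0.53, camera adjusted p = 2.28e-06; adjusted p = 0.557 with an estimated correlation; 7 adjusted over the list alone), with Hmgcs1 at -1.03 ± 0.28 (-0.61 without Vehicle-sham 2) and Nsdhl at -0.59 ± 0.17. Excitatory synapse genes had a median of -0.44 (camera adjusted p = 9.27e-06; adjusted p = 0.557 with an estimated correlation; 7 adjusted over the list alone), and chaperones and unfolded protein genes -0.32 (camera adjusted p = 0.00115; adjusted p = 0.557 with an estimated correlation; 0 adjusted over the list alone), with Manf at -0.42 ± 0.13. Higher lists were microglia activation, with a median of 0.77 (camera adjusted p = 0.000894; adjusted p = 0.637 with an estimated correlation; 7 adjusted over the list alone), and complement, with a median of 0.56 (camera adjusted p = 0.000894; adjusted p = 0.637 with an estimated correlation; 4 adjusted over the list alone). Clec7a, a microglial lectin, had 3.2 ± 0.89 and C3 1.75 ± 0.52. Fibroblast and matrix genes were higher as well, with a median of 0.6 and 17 of 20 above 0 (camera adjusted p = 0.00244; adjusted p = 0.557 with an estimated correlation; 3 adjusted over the list alone), Col6a2 at 1.63 ± 0.47 and Col1a1 at 0.88 ± 0.25. Reactive astrocyte genes had a median of 0.62 (camera adjusted p = 0.00558; adjusted p = 0.64 with an estimated correlation), and lost the call without TCF-CCI 1 (camera adjusted p = 0.074).

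The count of 3 genes was small and unsteady. It was 0 without Vehicle-sham 2, 4 or 5 or without TCF-CCI 1, 2, 3 or 4, 1 without TCF-CCI 5 and 6 without Vehicle-sham 3, and Dnajb13 also lost its call without Vehicle-sham 1, TD-CCI 3 or TD-CCI 5. With the replicate block the genes called were Tmem114, Enox2 and Vps29, and Dnajb13 was not among them. At an unadjusted p under 0.05 edgeR had 3788 genes, 1329 higher and 2459 lower, DESeq2 called 249 and limma voom with sample quality weights 388. Camera called 21 of 41 lists, 7 of them in all 15 alternative fits with the preset correlation, and 13 without TCF-CCI 1.

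TNF-CCI versus Vehicle-sham had 542 called genes, 360 higher and 182 lower (edgeR). Gfap averaged 4200 ± 2560 CPM against 1050 ± 392 (SD, n = 5 each; 1.99 ± 0.4, edgeR adjusted p = 0.0198) and Cd68 9.04 ± 3.99 against 1.31 ± 0.541 CPM (2.76 ± 0.57, edgeR adjusted p = 0.0201), both above every sham library in 5 of 5. Bdnf averaged 34.3 ± 18.8 CPM and did not pass (-0.52 ± 0.27, edgeR adjusted p = 0.285; -0.28 without Vehicle-sham 2 and -0.91 without TNF-CCI 1). Of the rising genes without overlap between the groups, those of largest change at 1 CPM or more included Lilrb4, an inhibitory receptor of myeloid cells (11.4 ± 14.6 against 0.129 ± 0.117 CPM; 6.42 ± 1.31), the macrophage elastase Mmp12 (5.99 ± 1.38), the acute phase serpin Serpina3n (5.31 ± 1.17) and Igsf7 (4.45 ± 1.1). TNF-CCI 2 held 37.4 CPM of Lilrb4, 8.02 of Mmp12 and 6.23 of Igsf7, against at most 7.26, 1.42 and 0.951 in the other TNF-CCI libraries. Without it Lilrb4 had 5.22 and Mmp12 4.88, and Igsf7 had 3.18 and did not pass. Serpina3n rested on TNF-CCI 5, which held 7.03 CPM against 0.205 to 1.05 in the other TNF-CCI libraries, and had 3.6 without passing when that library was left out. Of 22 microglia activation genes 13 rose (18 adjusted over the list alone; median 1.55, camera adjusted p = 5.53e-14; adjusted p = 0.234 with an estimated correlation). Spp1 (chromosome 14, 5308885 to 5315120) averaged 44 ± 35.4 against 2.12 ± 0.904 CPM (4.36 ± 0.82, edgeR adjusted p = 0.0198), and Tyrobp, the signalling adaptor of Trem2, rose by 1.63 ± 0.31. Of 11 markers of resting microglia 4 rose (8 adjusted over the list alone), with Csf1r at 1.59 ± 0.35 and Aif1 at 1.06 ± 0.26. Of 20 reactive astrocyte genes 9 rose (16 adjusted over the list alone; median 1.52, camera adjusted p = 1.17e-11; adjusted p = 0.264 with an estimated correlation), with the protease inhibitor Timp1 at 2.7 ± 0.54. TNF-CCI 1 held 62.3 CPM of Timp1 and the other TNF-CCI libraries 6.47 to 10.6, and without TNF-CCI 1 the gene had 1.51 and did not pass. Of 18 complement genes 7 rose (13 adjusted over the list alone; median 1.23, camera adjusted p = 1.18e-10; adjusted p = 0.285 with an estimated correlation), with Serping1 at 3.25 ± 0.61 and C3 at 2.71 ± 0.54.

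Interferon response genes all lay above 0 in TNF-CCI, 32 of 32, with a median of 0.63 (camera adjusted p = 1.19e-10; adjusted p = 0.41 with an estimated correlation). Of these 1 gene rose, Ifitm3, a membrane protein against viral entry (1.92 ± 0.43; 1 adjusted over the list alone). The sham libraries were uneven in this list. Its mean was 3.96 log2 CPM in Vehicle-sham 5, 1.88 to 2.41 in the other sham libraries and 2.79 to 4.04 in TNF-CCI. Among 23 cytokine and chemokine genes Tgfb1 rose (1.87 ± 0.4; 13 adjusted over the list alone; median 1.21, camera adjusted p = 4.87e-09; adjusted p = 0.321 with an estimated correlation). Among 20 matrix genes 3 rose (8 adjusted over the list alone; median 0.77, camera adjusted p = 7.63e-05; adjusted p = 0.317 with an estimated correlation), with Col1a1 at 1.24 ± 0.25 and Fn1 at 1.2 ± 0.26. Among falling genes chosen in the same way were the acetyltransferase Nat8f2 (-1.83 ± 0.49), Eaf2 (-1.41 ± 0.35), Sptssb, a subunit of serine palmitoyltransferase (-1.41 ± 0.37), and Pdzrn4 (-1.34 ± 0.28). Hmgcs1 (chromosome 2, 51649368 to 51667100) fell from 305 ± 159 to 127 ± 21 CPM (-1.27 ± 0.28, edgeR adjusted p = 0.0231) and Idi1 by -1.29 ± 0.35 (-0.81 without Vehicle-sham 2), the 2 of 18 cholesterol synthesis genes that fell (6 adjusted over the list alone; median -0.44, camera adjusted p = 1.99e-06; adjusted p = 0.321 with an estimated correlation). Vehicle-sham 2 held 590 CPM of Hmgcs1 and the other sham libraries 223 to 245. Of 21 excitatory synapse genes Gria2 fell (-0.8 ± 0.21; 7 adjusted over the list alone; median -0.37, camera adjusted p = 3.63e-06; adjusted p = 0.285 with an estimated correlation).

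The adjusted p of the 542 genes lay close to the threshold, from 0.0198 with a median of 0.0337 (edgeR). The count was 0 without Vehicle-sham 4, TNF-CCI 1 or TNF-CCI 5, where the smallest edgeR adjusted p was 0.0613, 0.0667 and 0.0553, and 0 without Vehicle-sham 2 and 3 together (0.0617). It was 929, 287, 174 and 1107 without Vehicle-sham 1, 2, 3 or 5, and 1563 and 322 without TNF-CCI 2 or 3. TNF-CCI had the deepest libraries and the lowest mitochondrial rRNA share. DESeq2 called 1370 genes and limma voom with sample quality weights 969, and 4215 had an unadjusted p under 0.05 in edgeR. In 350 of the 542 genes the groups did not overlap, and of all tested genes 3.51% had no overlap, where chance gives 0.794%.

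The supplements were next compared with Vehicle-CCI, to test a difference among injured animals. In TD-CCI the fibroblast and matrix list was higher, with a median of 0.58 and 17 of 20 members above 0 (camera adjusted p = 6.36e-10; adjusted p = 0.133 with an estimated correlation), and 8 members passed when adjusted over the list alone. The list mean was highest in TD-CCI 1, at 4.48 log2 CPM. It was 3.07 to 3.7 in the other TD-CCI libraries and 2.64 to 3.26 in Vehicle-CCI. Col1a1 averaged 11.4 ± 3.18 CPM in TD-CCI and 5.25 ± 1.51 in Vehicle-CCI (SD, n = 5 each; 1.11 ± 0.25, edgeR adjusted p = 1), and Col1a2, the second chain of type I collagen (chromosome 4, 32563938 to 32598868), 18.9 ± 5.66 against 7.58 ± 1.41 CPM (1.32 ± 0.35, edgeR adjusted p = 1), higher than every Vehicle-CCI library in 5 of 5. All 22 ribosomal protein genes lay below 0 (median -0.32, camera adjusted p = 7.24e-10; adjusted p = 0.543 with an estimated correlation). The level of short over long genes, a library measure, averaged -0.17 ± 0.217 log2 units in TD-CCI and 0.13 ± 0.155 in Vehicle-CCI (SD, n = 5 each). Red blood cell markers had a median of -0.97 (camera adjusted p = 4.92e-06; adjusted p = 0.543 with an estimated correlation), with the globin Hba-a3 at -1.49 ± 0.56 (-0.91 without Vehicle-CCI 3). These 3 lists were called in all 15 alternative fits with the preset correlation, of 17 called. Gfap (0.29 ± 0.39), Cd68 (-0.08 ± 0.52) and Bdnf (-0.08 ± 0.27) did not pass.

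The choroid plexus list had a median of -1.87 in TD-CCI versus Vehicle-CCI (camera adjusted p = 0.000922; adjusted p = 0.676 with an estimated correlation; 7 lower adjusted over the list alone), and did not pass without Vehicle-CCI 3 (camera adjusted p = 0.732). Ttr, the thyroxine carrier that the choroid plexus secretes, averaged 767 ± 1670 CPM in Vehicle-CCI and 17.6 ± 20.6 in TD-CCI (n = 5 each), and Vehicle-CCI 3 alone held 3760. Homeostatic astrocyte genes had a median of 0.19 (camera adjusted p = 0.000263; adjusted p = 0.543 with an estimated correlation) and did not pass without TD-CCI 4 (0.167 by camera). For single genes edgeR called 0, with 368 at an unadjusted p under 0.05, where 0.05 of the tested genes is 1053. Other splits of the same libraries gave 249 to 3021. DESeq2 called 1, Irx2, and limma voom with sample quality weights 0. Camera called 11 lists without TD-CCI 5.

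Myelin genes were lower in TCF-CCI than in Vehicle-CCI, all 16 below 0 with a median of -0.35 (camera adjusted p = 9.39e-06; adjusted p = 0.554 with an estimated correlation; 0 adjusted over the list alone). The myelin lipid enzyme Ugt8 had -0.49 ± 0.25 and the proteolipid Mal -0.55 ± 0.3, which were -0.26 and -0.27 without Vehicle-CCI 4. All 22 ribosomal protein genes (median -0.22, camera adjusted p = 5.33e-05; adjusted p = 0.633 with an estimated correlation) and all 18 chaperone and unfolded protein genes (median -0.2, camera adjusted p = 0.000138; adjusted p = 0.518 with an estimated correlation) lay below 0. The level of short over long genes averaged -0.116 ± 0.16 log2 units in TCF-CCI and 0.13 ± 0.155 in Vehicle-CCI (SD, n = 5 each). Glucocorticoid response genes had a median of -0.24 (camera adjusted p = 0.000415; adjusted p = 0.351 with an estimated correlation), with the kinase Sgk1 at -0.51 ± 0.27. Vehicle-CCI 3 held 126 CPM of Sgk1 and the other Vehicle-CCI libraries 42 to 68.6, and without it the gene was at -0.19. These 4 lists were called in all 15 alternative fits with the preset correlation, of 18 called. Microglia activation genes had a median of -0.4 (camera adjusted p = 0.000138; adjusted p = 0.633 with an estimated correlation), with Cd63 at -0.45 ± 0.19, and lost the call without Vehicle-CCI 1 (0.152 by camera) or TCF-CCI 5 (0.174).

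Among single genes of TCF-CCI versus Vehicle-CCI, Rbfa (-0.69 ± 0.2), C1qtnf9 (-1.24 ± 0.34) and the iron hormone Hamp (-1.71 ± 0.51) were named for their small p among lower genes, and the bradykinin receptor Bdkrb2 (1.98 ± 0.6), Henmt1 (0.48 ± 0.15) and Kcng3 (1.24 ± 0.41) of the higher ones. None passed. Gfap (-0.28 ± 0.39), Cd68 (-0.84 ± 0.53; -0.22 without Vehicle-CCI 1) and Bdnf (-0.16 ± 0.27) did not pass either. The edgeR count was 0, with 304 at an unadjusted p under 0.05 (1053 by chance). The counts by DESeq2 and by limma voom with sample quality weights were 0. The number of lists called by camera was 9, 10 and 28 without Vehicle-CCI 1, 2 or 4, and 7 without TCF-CCI 5.

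TNF-CCI had higher interferon, microglial and astrocyte lists than Vehicle-CCI. Interferon response genes had a median of 0.35 with 27 of 32 above 0 (camera adjusted p = 6.11e-06; adjusted p = 0.873 with an estimated correlation), microglia activation genes 0.25 with 21 of 22 above 0 (camera adjusted p = 3.63e-05; adjusted p = 0.873 with an estimated correlation), and reactive astrocyte genes 0.38 (camera adjusted p = 0.000108; adjusted p = 0.873 with an estimated correlation). Timp1 had a log2 fold change of 1.55 ± 0.51 (0.36 without TNF-CCI 1), Serpina3n of 2.64 ± 0.9 (0.94 without TNF-CCI 5) and Apoe, the main lipid carrier of the brain, of 0.6 ± 0.27. Each of these 3 lists lost the call without Vehicle-CCI 4 (0.21, 0.053 and 0.053 by camera), the library of lowest Cd68 in its group. Immediate early genes, which neuronal activity induces, had a median of 0.22 (camera adjusted p = 0.0062; adjusted p = 0.873 with an estimated correlation), with Arc at 1.09 ± 0.39 and Fosb at 0.67 ± 0.24 (0.22 and 0.41 without TNF-CCI 1), and lost the call without TNF-CCI 1 (0.241 by camera). The choroid plexus list had a median of -1.38 (camera adjusted p = 0.0138; adjusted p = 0.873 with an estimated correlation), and lost the call without Vehicle-CCI 3 (0.487 by camera) or TNF-CCI 4 (0.254).

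Of the 11 lists called in TNF-CCI versus Vehicle-CCI 0 were called in all 15 alternative fits with the preset correlation, and camera called 17, 7 and 6 without Vehicle-CCI 2, 3 or 4. Gfap (0.89 ± 0.39; 0.53 without TNF-CCI 1), Cd68 (0.34 ± 0.52) and Bdnf (0.34 ± 0.27) did not pass. The quinone reductase Cryz was higher than every Vehicle-CCI library in 5 of 5 (0.82 ± 0.2, edgeR adjusted p = 0.904). Lox, the enzyme that crosslinks collagen (chromosome 18, 45964311 to 46041477), averaged 33 ± 69.2 against 1.78 ± 0.315 CPM (n = 5 each; 4.2 ± 0.97, edgeR adjusted p = 0.904), of which TNF-CCI 1 held 157, and had 0.19 without that library. EdgeR called 0 genes, with 729 at an unadjusted p under 0.05 (1053 by chance). DESeq2 called 1, LOC120097130 (-4.97), and limma voom with sample quality weights 0.

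Between supplements, F3, the tissue factor that starts coagulation (chromosome 2, 209827061 to 209838666), averaged 25.1 ± 2.17 CPM in TNF-CCI and 15.6 ± 2.33 in TD-CCI (SD, n = 5 each; 0.68 ± 0.14, edgeR adjusted p = 0.817), higher in 5 of 5. It was the 1 gene that DESeq2 called in that comparison (0.69, DESeq2 adjusted p = 0.0154). EdgeR called 0 genes there, with 517 at an unadjusted p under 0.05 (1053 by chance), and limma voom with sample quality weights 0. Fosb was also higher in 5 of 5 (1.07 ± 0.25), as was Asb15 (5.35 ± 1.17, at 8.43 ± 18.1 CPM in TNF-CCI; 0.66 without TNF-CCI 2). The hormone precursor Pomc had -3.34 ± 0.81 at 19.1 ± 33.3 CPM in TD-CCI, 78.1 of it in TD-CCI 1 (-1.19 without that library), and Kcnq1 was lower than every TD-CCI library in 4 of 5 (-1.07 ± 0.28). In TNF-CCI versus TCF-CCI, Gfap had a log2 fold change of 1.18 ± 0.39 (edgeR adjusted p = 0.937) and Cd68 of 1.17 ± 0.53 (edgeR adjusted p = 0.953). Nat8f2 (-2.17 ± 0.49) and the mitochondrial histidine tRNA Trnh (-1.02 ± 0.28) were lower than every TCF-CCI library in 5 of 5. EdgeR called 0 of these, with 1079 at an unadjusted p under 0.05 (1053 by chance). DESeq2 called 6 and limma voom with sample quality weights 12, of which 5 were mitochondrial tRNAs (Trnr, Trnh, Trns2, Trnl2 and Trnp). The mitochondrial rRNA share averaged 4.87% in TNF-CCI and 7.57% in TCF-CCI. In TD-CCI versus TCF-CCI the carboxypeptidase Cpz had 1.44 ± 0.34 and Dmac2 -0.56 ± 0.15. The counts there were 0 by edgeR, DESeq2 and limma voom with sample quality weights. EdgeR had 403 at an unadjusted p under 0.05 (1053 by chance).

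For an effect shared by the supplements, the mean of the 3 was compared with Vehicle-CCI, 15 against 5 libraries. Col1a1 had a log2 fold change of 0.87 ± 0.21 (edgeR adjusted p = 1), higher than every Vehicle-CCI library in 11 of 15, and the endothelial Notch ligand Dll4 0.93 ± 0.27. Cltrn (-4.44 ± 1.04), Slco1a5 (-4.14 ± 1.04) and Kcnj13 (-3.45 ± 0.86), which like Ttr had their highest level in Vehicle-CCI 3, were named for their small p among lower genes, and had 1.16, 1.21 and 1.04 without Vehicle-CCI 3. EdgeR called 0, with 399 at an unadjusted p under 0.05 (1053 by chance). The counts by DESeq2 and by limma voom with sample quality weights were 0. Without TCF-CCI 4 edgeR called 3, those same Cltrn, Slco1a5 and Kcnj13.

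The injury score asked whether injury-responsive genes lay nearer to sham under a supplement. It averaged 0 ± 0.73 log2 units in Vehicle-sham (SD, n = 5), 1.62 ± 0.93 in Vehicle-CCI, 1.84 ± 0.36 in TD-CCI, 1.61 ± 0.56 in TCF-CCI and 2.17 ± 0.51 in TNF-CCI. Against Vehicle-CCI the difference was 0.22 in TD-CCI (exact permutation p = 0.627, adjusted 0.94), -0.01 in TCF-CCI (exact permutation p = 0.976, adjusted 0.976) and 0.55 in TNF-CCI (exact permutation p = 0.27, adjusted 0.81). The score genes were chosen from all 4 CCI groups, the supplement groups among them, so a gene that the supplements brought back towards sham was less apt to enter, and the score cannot show an absence of recovery. The smallest p that 5 against 5 libraries allow is 0.0079, and no difference exceeded the spread between libraries. Leaving out 1 library moved the difference between -0.13 and 0.47 in TD-CCI, -0.27 and 0.23 in TCF-CCI, and 0.16 and 0.82 in TNF-CCI. The lowest of each range came without Vehicle-CCI 4, and the highest without Vehicle-CCI 2 in TD-CCI and TCF-CCI and without Vehicle-CCI 1 or 2 in TNF-CCI. With the 200 genes of smallest p in each direction and without Vehicle-sham 2 and 3 the differences were 0, -0.11 and 0.32.

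**Figure D5:**
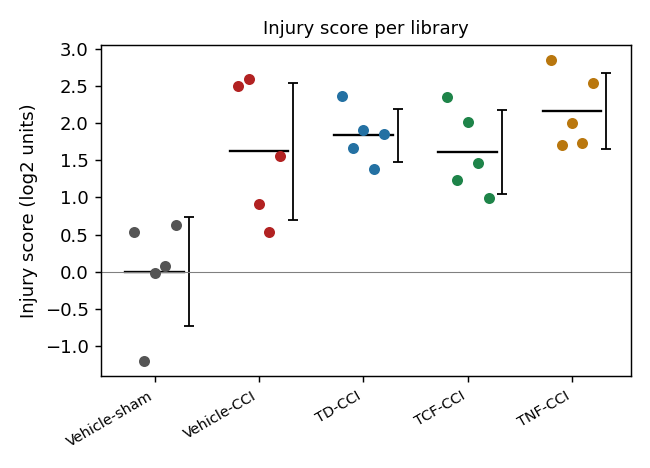
Injury score in log2 units for each of the 25 libraries, centred on the sham mean. Points are libraries, horizontal lines are group means and vertical bars are SD (n = 5); the Vehicle-CCI libraries ran from 0.54 to 2.6, a range that covered the other CCI group means of 1.61 to 2.17.

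The authors' deposited table of Vehicle-CCI over control had 70 genes at a DESeq2 adjusted p under 0.05, 66 of them higher. In the authors' deposited table the DESeq2 count was 509 for TD-CCI (428 higher), 423 for TCF-CCI (213 higher) and 797 for TNF-CCI (614 higher). For Gfap the authors' deposited table had log2 fold changes of 1.11, 1.4, 0.83 and 2 in Vehicle-CCI, TD-CCI, TCF-CCI and TNF-CCI, with DESeq2 adjusted p of 0.131, 1.37e-05, 0.181 and 6.17e-05. For Cd68 the authors' deposited table had 2.46, 2.35, 1.61 and 2.78, with DESeq2 adjusted p of 0.0208, 7.43e-10, 0.0584 and 1.19e-10. For Bdnf the authors' deposited table had -0.86, -0.96, -1.02 and -0.54, with DESeq2 adjusted p of 0.197, 0.0179, 0.0215 and 0.517. Of the genes called in the authors' deposited table and tested here (70, 506, 422 and 789), all had the same sign in the edgeR fit of the same counts. At an unadjusted p under 0.05 in edgeR were 70, 501, 417 and 788 of them, while 0, 0, 3 and 446 were among the edgeR calls. Both sources rest on the same libraries.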

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

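The tests of a change in the medians without Vehicle-sham 2 or Vehicle-CCI 3, of gene length, of thinned counts and of the mitochondrial rRNA covariate were chosen only after the result was seen; the splits of the libraries and the counts with each library left out were planned.

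In 16 of 83 groups of 5 libraries, 1 library lay far from the other 4, where chance gives about 1 in 20 groups (4.15 of 83). Several of the genes were named for a large change or a small p, which 1 library can carry, so the excess over chance has no weight for them. For library measures these were the mitochondrial rRNA share of TNF-CCI 2 (10.9%, the others 2.95 to 4.17), the Bc1 share of Vehicle-sham 2 (1.92%, the others 0.046 to 0.46) and the number of receptor genes with a count in TCF-CCI 2 (370, the others 139 to 182) and TNF-CCI 2 (381, the others 132 to 162). TCF-CCI 4 stood apart in its TMM factor (0.988, the others 1.05 to 1.07) and in the level of short over long genes (0.16, the others -0.24 to -0.14). Among genes, in CPM, they were Bdnf in TNF-CCI 1 (67.2, the others 22.2 to 33), Lilrb4 in Vehicle-sham 1 (0.331, the others 0.0295 to 0.114) and TNF-CCI 2 (37.4, the others 3.58 to 7.26), and Hmgcs1 in Vehicle-sham 2 (590, the others 223 to 245). Ttr stood apart in Vehicle-CCI 3 (3760, the others 4.86 to 50.6) and TD-CCI 1 (54.3, the others 6.55 to 12.3), Lox in TNF-CCI 1 (157, the others 1.49 to 2.97) and Asb15 in TNF-CCI 2 (40.9, the others 0.247 to 0.488). Gpnmb did so in Vehicle-sham 5 (12.2, the others 2.44 to 4.69) and Pomc in TD-CCI 1 (78.1, the others 1.09 to 12.1).

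More genes fell than rose in the mean of the 4 CCI groups, and the falling ones leaned on Vehicle-sham 2, the library of highest mitochondrial rRNA share. Their median log2 fold change of -0.65 became -0.37 without it, against -0.74, -0.66, -0.72 and -0.71 without Vehicle-sham 1, 3, 4 or 5, so RNA quality or content of that library may account for part of the fall. Short genes stood high in that library (1.18 for short over long genes), and the falling genes had 0.916 of the median length of tested genes, with 15.2% at most 1000 bases against 11.5%, so a part played by gene length stays open. The rising genes had a median of 1.15, and 1.13 without Vehicle-sham 2, which argues against that library as their cause. All 472 had an unadjusted p under 0.05 without it, yet edgeR still called 6, against 369, 213, 169 and 384 without Vehicle-sham 1, 3, 4 or 5, and why the calls ended was not tested. A loss of neuronal transcripts after injury stays open for the falling genes.

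The choroid plexus list was lower in TD-CCI and TNF-CCI than in Vehicle-CCI, with medians of -1.87 and -1.38. Without Vehicle-CCI 3 the medians were 0.01 and 0.27, and without each other Vehicle-CCI library they stayed between -2.14 and -1.54. Choroid plexus tissue in the sample of Vehicle-CCI 3, at 3760 CPM of Ttr, is thus a candidate source of the difference. In TCF-CCI versus Vehicle-CCI the list did not pass (median -0.75, camera adjusted p = 0.0755) and its median was 1.4 without Vehicle-CCI 3, with 476 CPM of Ttr in TCF-CCI 4. Whether such tissue came from dissection was not tested.

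TNF-CCI had 542 genes called over sham, against 0, 0 and 3 in Vehicle-CCI, TD-CCI and TCF-CCI (edgeR). In the authors' deposited tables the DESeq2 counts were 797 against 70, 509 and 423. DESeq2 over the 25 libraries called 1370 against 245, 244 and 249. An edgeR fit of only the groups compared narrowed the gap between TNF-CCI and TD-CCI. Over Vehicle-CCI 0 genes were called in TNF-CCI (edgeR; 729 at an unadjusted p under 0.05, 1053 by chance, 1 by DESeq2 and 0 by limma voom with sample quality weights). The 360 rising and 182 falling genes had medians of 1.58 and -0.99 in TNF-CCI, 1.23 and -0.62 in Vehicle-CCI, 1.15 and -0.69 in TD-CCI and 0.9 and -0.73 in TCF-CCI, values that share their sham libraries and were selected in TNF-CCI. With every library thinned to 27.3 M counts edgeR called 502, which argues against depth. With the mitochondrial rRNA share as a covariate edgeR called 103, 97 higher and 6 lower: the median of the 360 rising genes was 1.53 (1.58 before), which argues against that share for their fold, while that of the 182 falling genes was -0.6 (-0.99 before), which leaves the share open for them. The count was 929, 287, 174 and 1107 without Vehicle-sham 1, 2, 3 or 5, 1563 and 322 without TNF-CCI 2 or 3, and 0 without Vehicle-sham 4, TNF-CCI 1 or TNF-CCI 5. Whether the response differed between supplements was tested in the direct comparisons, and a stronger response in TNF-CCI stays open as a hypothesis.

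For the real groups, splits of the same libraries into groups of the same sizes gave the following. In TCF-CCI versus sham 1 of 50 splits, the real one, had as many calls (real 3, highest other 0). In the mean of the 4 CCI groups versus sham it was also 1 of 50 (real 1248, highest other 182). These shares were not adjusted over the comparisons. In TNF-CCI versus sham it was 2 of 50 (real 542), since 1 other split called 1543, and a further split called 492. With such counts from other splits, this test cannot exclude chance for the 542 genes. A structure of the samples other than the groups could also give such counts. The split of 1543 calls exchanged only Vehicle-sham 1 and TNF-CCI 2. TNF-CCI 2 had the highest mitochondrial rRNA share of its group (10.9%), and without it edgeR called 1563 in the real groups. With a real count of 0 all splits give as many, 25 of 25 each, so chance cannot be excluded. The highest other was 215 in Vehicle-CCI versus sham, 1 in TD-CCI versus sham, 0, 11 and 0 in TD-CCI, TCF-CCI and TNF-CCI versus Vehicle-CCI, 0 in TD-CCI versus TCF-CCI, 6 in TNF-CCI versus TD-CCI, 26 in TNF-CCI versus TCF-CCI and 21 in the mean of the 3 supplements. The 215 of Vehicle-CCI versus sham, with 0 in the real groups, came from a split that exchanged only Vehicle-sham 2 and Vehicle-CCI 4. Vehicle-CCI 4 had the lowest Cd68 of its group, and without it edgeR called 368 in the real groups. Neither this split nor that of 1543 calls tells a structure of the samples apart from the real grouping, most of which they kept.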

How the results depend on the processing

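The fits without 2 sham libraries, without 4 libraries and with the mitochondrial rRNA share as a covariate were chosen only after the result was seen. The counts of called genes depended on the tool and on single libraries. No named gene value that was called changed sign, while some that were not called did, such as Cltrn, Kcnj13 and Slco1a5 in the mean of the 3 supplements without Vehicle-CCI 3 (1.16, 1.04 and 1.21). When 1 library was left out, 2211 values stayed on their side of the threshold, 129 lost and 27 gained a call and 18 moved, and under the other settings these were 2244, 111, 71 and 19. Where a setting is not explained by fewer libraries or genes, the cause was not tested.

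DESeq2 called 245, 244, 249 and 1370 genes in Vehicle-CCI, TD-CCI, TCF-CCI and TNF-CCI versus sham, 2338 in the mean of the 4 CCI groups, 1 each in TD-CCI and TNF-CCI versus Vehicle-CCI and in TNF-CCI versus TD-CCI, and 6 in TNF-CCI versus TCF-CCI. Limma voom with sample quality weights called 2, 388 and 969 in TD-CCI, TCF-CCI and TNF-CCI versus sham and 12 in TNF-CCI versus TCF-CCI. A block for the replicate number gave 1 (Kcnk6), 45 and 1190 in Vehicle-CCI, TD-CCI and TNF-CCI versus sham. Libraries of the same number correlated at a median of 0.12 (27 of 50 pairs over 0.1) and others at -0.02 (43 of 200), and 11 of 25 libraries correlated best with 1 of their own number. This is a hint from the data that libraries of 1 number share something, but not every pair was over 0.1 and the labels give no meaning to the numbers, so the block stayed an alternative. The title number as a covariate gave 70, 5 and 1527 in Vehicle-CCI, TCF-CCI and TNF-CCI versus sham and 2515 in the mean of the 4 CCI groups. No filter gave 1, 0 and 2070 in TD-CCI and TCF-CCI versus sham and the mean of the 4 CCI groups. Only the groups compared gave 139, 1 and 197 in TD-CCI, TCF-CCI and TNF-CCI versus sham. An adjusted p under 0.10 gave 3 and 1583 in TD-CCI and TNF-CCI versus sham and 2811 in the mean of the 4 CCI groups (edgeR). Without the 2 sham libraries of high mitochondrial rRNA, and without 4 libraries, edgeR called 0 in TCF-CCI and TNF-CCI versus sham and in the mean of the 4 CCI groups, and with the rRNA share as a covariate 0, 103 and 168. Leaving out 1 library of the groups compared gave 0 to 368, 0 to 2, 0 to 6 and 0 to 1563 in the 4 CCI groups versus sham, 14 to 2117 in their mean and 0 to 3 in the mean of the 3 supplements.

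Of the lists, 0 were called in each of the 7 comparisons with an estimated correlation, and fry called 0, 5, 0 and 6 in the 4 CCI groups versus sham and 0, 0 and 0 versus Vehicle-CCI. Without 4 libraries camera called 5 in TD-CCI and 7 in TNF-CCI versus Vehicle-CCI, and without the 2 sham libraries 11 in TCF-CCI versus Vehicle-CCI. Leaving out 1 library gave 16 to 23, 16 to 24, 13 to 23 and 17 to 23 lists in the 4 CCI groups versus sham, and 11 to 20, 7 to 28 and 6 to 17 versus Vehicle-CCI. The injury score difference of TD-CCI was 0, and that of TNF-CCI 0.32, with the 200 genes of smallest p in each direction and without the 2 sham libraries (0.04 and 0.24 without 4 libraries), and with 1 library left out the differences ran from -0.13 to 0.47, -0.27 to 0.23 and 0.16 to 0.82. With all libraries thinned to 27.3 M counts 481 of the 542 genes of TNF-CCI versus sham were still called.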
